A study of Mus musculus with 9 samples.

How the data were processed

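The deposited table holds raw counts of reads per gene, with 1 column for each of the 9 libraries. Per the submitters' processing notes, reads were aligned with STAR 2.7.3a to the mouse genome build mm10 and counted per gene with featureCounts. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so genes that share exon bases or belong to families of close copies carry uncertain counts. Values in the table were whole numbers, no 2 replicate columns were duplicates of each other, and 0 columns were left without a sample. Gene symbols were used as deposited, and positions were taken from GENCODE M21 on GRCm38 (mm10).

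Libraries were grouped as GF, EcN and kfiCD by the treatment the labels give, with 3 libraries per group and 1000 sorted cells per library. The sample titles and count columns of the kfiCD group read KIF instead, and every kfiCD value rests on both names meaning the same mutant. Total counts were 3875213, 4417699 and 5195048 in GF replicates 1, 2 and 3, 4203317, 3564853 and 4151745 in EcN, and 4090661, 4182164 and 3820003 in kfiCD. At this depth a floor of 3 counts corresponds to 0.577 to 0.842 CPM. Reads carry no molecular identifiers, so such limits cover counting error only.

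The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a test is said to have been chosen later. Genes were filtered with filterByExpr by group, which left 11936, and libraries were scaled with TMM factors. The main test was edgeR's quasi-likelihood F test on the counts, with all 9 libraries in 1 model so that the groups share an estimate of the spread, no covariate, and Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.0748, a biological coefficient of variation of 27.4%. The 3 pairwise comparisons and a joint test of the 3 groups were made. The work used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

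Gene lists were written for regulatory T cells, Th17 and type 3 immunity, Th1, Th2, T follicular helper cells, T cell receptor activation, the naive and central memory state, co-inhibitory receptors, cytotoxic effectors, the interferon response, proliferation, glycolysis, oxidative phosphorylation, cholesterol synthesis, the unfolded protein response, NF-kB targets, and gut homing and tissue residency. A list of dissociation stress genes covered cell handling, and lists of B and plasma cells, macrophages and dendritic cells, stromal and endothelial cells, and CD8, gamma-delta and innate lymphocytes covered other cells. These 22 lists, each with at least 5 tested genes, were tested with camera at a preset correlation between genes of 0.01 and adjusted within each comparison. With a correlation estimated from the data, 0 lists were called in each of the 3 comparisons, the lowest adjusted p being 0.0964 for EcN against GF, 0.0610 for kfiCD against GF and 0.391 for kfiCD against EcN. The directional test fry, which asks whether a list's genes moved on balance in 1 direction, called 0 lists as well (lowest adjusted p 0.0805, 0.103 and 0.675), and its mixed test, for change in either direction, called 6, 1 and 0. Lists of neutrophil and mast cell, epithelial cell and red blood cell genes had too few measured members to test, and the CD4 T cell identity list was used for levels only.

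Genes were named by a fixed rule: for each comparison, up to 8 with the largest rise and fall among genes past the threshold that separate the groups and average at least 10 CPM, up to 3 members per list past the threshold, and a fixed panel. Since none passed, the rule took the 5 of lowest p in each direction under the same conditions, as values and not as changes. Clone names, mitochondrial genes and receptor segments were left out. List members named beside them passed when adjusted over the list alone or led their list by p.

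The tests were run on simulated counts drawn from the real means and library sizes, in 3 draws with 200 genes changed among 11936. For EcN against GF, 6.47% of genes changed 1.5-fold were recovered, 30.8% of those changed 2-fold and 77.3% of those changed 4-fold, and for kfiCD against GF 7.46%, 26.9% and 77.8%. False calls over the 3 draws numbered 10 and 17. A Th17 list changed 2-fold was called in every draw. Of the other lists, 1 was called for EcN against GF and 0 for kfiCD against GF. Each gene was drawn independently, so these list counts do not cover genes that vary together. In the real data the estimated correlation was, for instance, 0.52 for the regulatory T cell list in EcN against GF.

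Alternatives were DESeq2's size factors, library size alone, no filter, a filter of at least 10 CPM in 3 libraries, DESeq2, limma-voom with sample weights, a robust fit, a block for the replicate number, removal of receptor segments from library sizes, a threshold of 0.1, the 6 libraries of the compared groups alone, and each library left out in turn. T cell receptor beta V usage was compared by the share of the most used segment with exact permutation tests. The shared response to both strains was set beside simulated values. For these, all 9 libraries, GF included, were drawn without group differences and each gene independently. Mouse reads hold no record of the bacterial genotype, so the loss of the kfiCD genes was not checked.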

Results

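RNA was sequenced from CD4 T cells of the distal colon of C57BL/6J mice, with 1000 cells sorted for each library. The sort was run in duplicate passes and took live (DAPI-negative) cells that lacked the B cell marker CD19 and carried CD4 and the T cell receptor beta chain. The mice were germ-free (GF) or had carried a single bacterial strain for 14 days, either wild-type E. coli Nissle or its kfiCD mutant. The wild type (EcN) is a probiotic with a K5 polysaccharide capsule, and the mutant lacks that capsule. Each of the 3 groups had 3 libraries, and total counts ran from 3564853 to 5195048 per library. Of 55011 genes listed, 41062 had a count in at least 1 library and 11936 were expressed highly enough to test. Levels are normalised CPM (counts scaled to a common library size), given as mean ± SD over 3 libraries. Each library pools 1000 cells, so a change in the mix of cells cannot be told from one within cells. Log2 fold changes are given ± SE. The labels do not say that the replicates of a group are separate animals, so the p-values measure only the spread between these samples. T cell identity genes were high in all groups. Cd3d, a chain of the T cell receptor complex, was at 743 ± 33.6 CPM in GF, 637 ± 42.7 in EcN and 676 ± 19.8 in kfiCD (n = 3 each). The first principal component, with 23.8% of the variance, set EcN replicate 1, EcN replicate 2 and kfiCD replicate 1 apart from the other 6 libraries. EcN replicate 1 held 7600 CPM of Igha, the immunoglobulin A heavy chain, and 1165 CPM summed over fibroblast markers, which reached 2522 CPM in kfiCD replicate 1. Olfactory receptor genes, which T cells do not use, summed to 1416 CPM in EcN replicate 2 and 966 CPM in kfiCD replicate 1, against at most 250.8 CPM in the other 7 libraries.

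**Figure D1:**
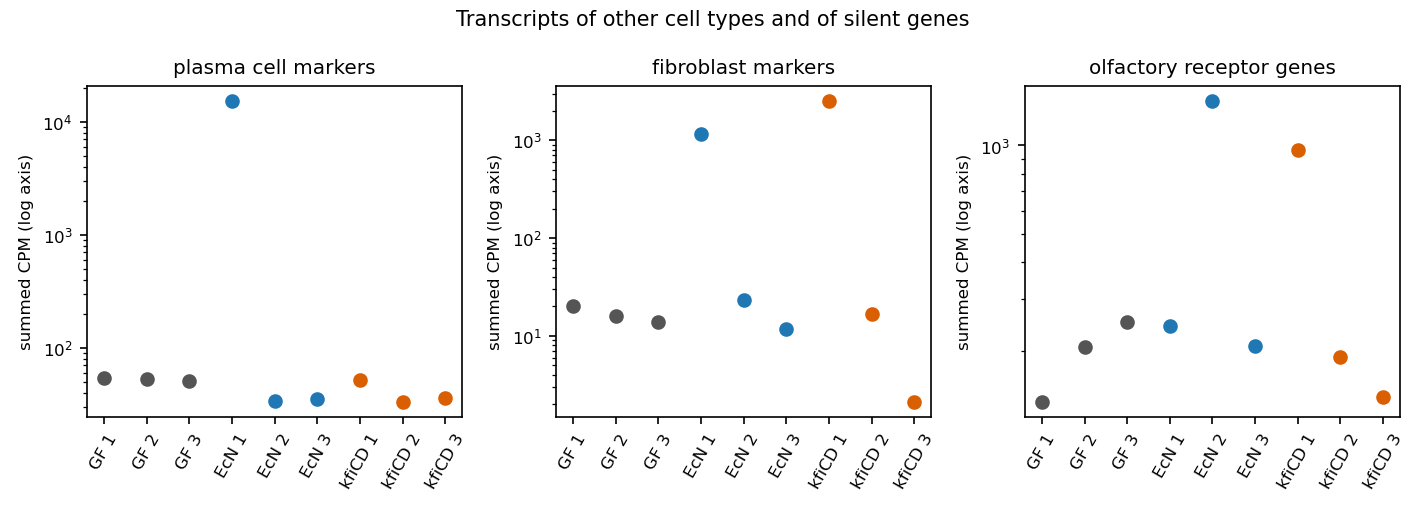
Summed CPM (log axis) of plasma cell markers, fibroblast markers and olfactory receptor genes in each of the 9 libraries, with 1 point per library. Fibroblast markers reached 2522 CPM in kfiCD replicate 1 and 1165 CPM in EcN replicate 1, and olfactory receptor genes 1416 CPM in EcN replicate 2 and 966 CPM in kfiCD replicate 1.

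The comparison of EcN with GF asked what colonization with the encapsulated strain did to colonic CD4 T cells. Transcripts of the Th17 programme rose. All 12 measured genes of the Th17 and type 3 immunity list lay above GF, with a median log2 fold change of 1.13 (camera adjusted p = 4.27e-11, and adjusted p = 0.0964 with an estimated correlation). Rorc, which encodes the Th17 lineage factor RORγt, stood at 18.9 ± 6.37 CPM in EcN and 7.09 ± 4.95 CPM in GF (2.63-fold, n = 3). Il23r, the receptor for the Th17-sustaining cytokine IL-23, stood at 10.2 ± 5.68 against 2.46 ± 1.41 CPM. Maf, a transcription factor that promotes Il10, had a log2 fold change of 0.85 ± 0.20. Genes of gut homing and tissue residency rose as a group (15 of 16 above GF, median 0.75, adjusted p = 8.36e-12, and adjusted p = 0.0964 with an estimated correlation). Itgae, the CD103 chain that binds epithelial E-cadherin, was 2.33-fold higher (183 ± 58.8 against 78.4 ± 26.7 CPM). The chemokine receptor genes Ccr2 and Ccr5 were 3.18-fold and 2.56-fold higher. Genes of the naive and central memory programme fell as a group. All 15 lay below GF (median -0.56, adjusted p = 1.27e-11, and adjusted p = 0.204 with an estimated correlation). Sell, the lymph node homing receptor L-selectin, was at 357 ± 79.0 against 558 ± 143 CPM, and Ccr7, which guides T cells into lymph nodes, at 3427 ± 942 against 5767 ± 922 CPM. The fall was mostly in EcN replicates 1 and 2, at a naive list score of -0.64 and -0.72, while EcN replicate 3 was at -0.21 and GF replicate 3 at -0.16. Without EcN replicates 1 and 2 and kfiCD replicate 1, a set chosen after seeing the data, the naive median was -0.26. That set leaves 1 EcN library, so the spread comes from the other groups and its calls decide nothing about EcN. Adjusted over the list alone, 7 Th17 genes passed as higher (Rorc, Rora, Il23r, Il1r1, Maf, Tmem176a and Tmem176b). So did 8 residency genes (Itgae, Cxcr6, Gpr15, Gpr55, Ccr5, Ccr2, Rgs1 and Prdm1), and 10 naive genes passed as lower. Over all genes tested, 0 passed. On the GRCm38 (mm10) genome with GENCODE M21 gene models, Rorc lies on chromosome 3 from 94372794 to 94398276, and Itgae on chromosome 11 from 73090583 to 73147446. Ccr2 and Ccr5 lie next to each other on chromosome 9, from 124101950 to 124113557 and from 124121543 to 124147699.

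**Figure D2:**
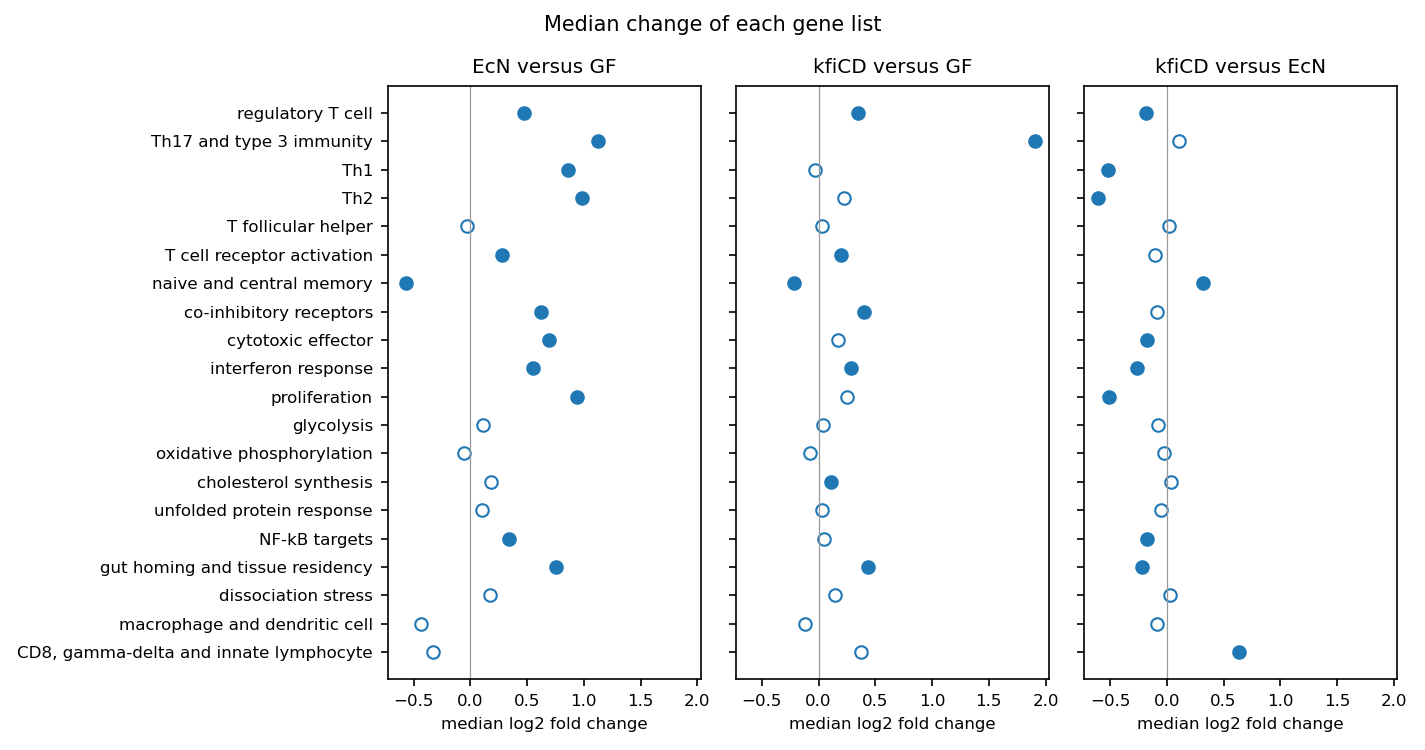
Median log2 fold change (horizontal axis) of tested gene lists in the 3 comparisons, with filled points where camera's adjusted p was under 0.05 and open points where it was not. The B and plasma cell list and the stromal and endothelial cell list are not shown. The Th17 list lay at 1.13 in EcN against GF and at 1.91 in kfiCD against GF, and the naive list at -0.56 and -0.21.

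Camera also called further T cell lists as higher in EcN, and with an estimated correlation 0 lists held. Other splits of the 6 EcN and GF libraries gave up to 15 called lists, against 12 for the real split. Wrong groupings can thus give as many calls. Genes of the interferon response rose (21 of 23 above GF, median 0.55, adjusted p = 1.64e-10, and adjusted p = 0.185 with an estimated correlation), among them Iigp1, an interferon-induced GTPase, at 43.2 ± 9.42 against 9.65 ± 6.23 CPM. Th1 genes rose (10 of 12 above GF, median 0.86, adjusted p = 1.27e-05, and adjusted p = 0.208 with an estimated correlation), led by Il12rb2, a chain of the IL-12 receptor, at 67.2 ± 0.858 against 35.3 ± 6.43 CPM. Il18rap, a chain of the IL-18 receptor, was at 129 ± 25.4 against 58.3 ± 12.2 CPM. Regulatory T cell genes rose (15 of 18, median 0.48, adjusted p = 1.06e-05, and adjusted p = 0.289 with an estimated correlation). Il10, an anti-inflammatory cytokine, was at 370.1 ± 136 against 178 ± 73.3 CPM, while Foxp3, the regulatory lineage factor, did not pass (900 ± 271 against 629 ± 170 CPM). The regulatory list score was 0.34 and 0.65 in EcN replicates 1 and 2 but 0.12 in EcN replicate 3, below GF replicates 1 and 3 at 0.13 and 0.14. The Th2 list rose (8 of 8, median 0.99, adjusted p = 0.000995, and adjusted p = 0.289 with an estimated correlation). So did proliferation genes (21 of 22, median 0.94, adjusted p = 3.10e-07, and adjusted p = 0.286 with an estimated correlation). Without EcN replicates 1 and 2 and kfiCD replicate 1, a set chosen after seeing the data that leaves only EcN replicate 3 for EcN, the Th2 median was -0.10, the proliferation median -0.03 and the Th1 median -0.0026. NF-kB targets rose (16 of 17, median 0.34, adjusted p = 0.000368, and adjusted p = 0.362 with an estimated correlation), and without those libraries their median was 0.01 and camera's direction downward. T cell receptor activation genes (19 of 20, median 0.28, adjusted p = 7.48e-05), co-inhibitory receptors (9 of 11, median 0.62, adjusted p = 0.000866) and cytotoxic effector genes (9 of 14, median 0.69, adjusted p = 0.00126) also rose. For these the values were adjusted p = 0.286, adjusted p = 0.283 and adjusted p = 0.208 with an estimated correlation. The activation score was 0.69 and 0.41 in EcN replicates 1 and 2, but 0.05 in EcN replicate 3 against 0.10 in GF replicate 1. Dissociation stress genes, a sign of cell handling, share Egr1 with the activation list. Their score was 0.43, 0.31 and -0.36 in EcN replicates 1, 2 and 3 and -0.34, 0.27 and 0.06 in GF. EcN replicate 3 was thus the lowest EcN library for this list as for the activation, NF-kB and regulatory lists. In GF, replicate 1 was lowest for stress but highest for activation (0.10) and NF-kB (0.02). A part of handling in the rise of these lists was not tested. Cd44, an adhesion receptor raised on activated T cells, was at 541 ± 33.4 against 283 ± 90.6 CPM. Havcr2, which encodes the inhibitory receptor TIM-3, was at 45.9 ± 16.1 against 16.1 ± 11.3 CPM, and the protease gene Gzmb at 508 ± 155 against 203 ± 115 CPM. Adjusted over the list alone, 5 regulatory, 4 Th1, 1 Th2, 3 activation, 2 co-inhibitory, 2 cytotoxic and 5 interferon genes passed as higher. For proliferation and NF-kB that count was 0, and over all genes tested it was 0 for each list.

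Gene by gene, edgeR called 0 of 11936 genes between EcN and GF at an adjusted p under 0.05, and 313 with no low-count filter. At an unadjusted p under 0.05 there were 1018 (646 higher and 372 lower), where chance gives 597. Other splits of these 6 libraries gave from 261 to 928, so a wrong grouping can also exceed 597. DESeq2 called 101 genes, 95 of them higher in EcN, among them Itgae, Ccr5, Iigp1 and Il12rb1, and limma-voom called 0. The genes of lowest p above GF were Nmrk1, a nicotinamide riboside kinase (74.3 ± 8.69 against 29.6 ± 4.61 CPM), Cipc, an inhibitor of the circadian factor CLOCK (79.6 ± 4.29 against 38.9 ± 3.57 CPM), and Furin, a proprotein convertase (361 ± 118 against 134 ± 15.9 CPM). Each of them had adjusted p = 0.0563. Ern1, the endoplasmic reticulum stress sensor IRE1, and Ly6a, which encodes Sca-1, had log2 fold changes of 1.49 ± 0.24 and 1.66 ± 0.27 (adjusted p = 0.0737 each). Below GF lay Itm2a (-0.83 ± 0.19), Pecam1, an adhesion molecule (-0.66 ± 0.15), Ifngr2, an interferon gamma receptor chain (-0.64 ± 0.15), Bambi-ps1 (-0.81 ± 0.20) and Traf3ip3 (-0.51 ± 0.13). Their adjusted p ran from 0.195 to 0.252. All 3 EcN libraries lay beyond all 3 GF libraries for 834 genes upward and 790 genes downward, 13.6% of the genes tested, where chance gives 10%. Of the 299 genes on all the fixed lists, 29 passed when adjusted over these genes, 26 of them higher and 3 lower (Pecam1, Ccr7 and Als2cl). That count was 0 without GF replicate 1, 2 without GF replicate 2, 3 without EcN replicate 1, 4 without EcN replicate 2, 46 without kfiCD replicate 1 and 1 without all 3 of EcN replicates 1 and 2 and kfiCD replicate 1, where 1 EcN library is left. Igkc, an immunoglobulin light chain among the 26, stood at 5675 CPM before scaling in EcN replicate 1.

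**Figure D3:**
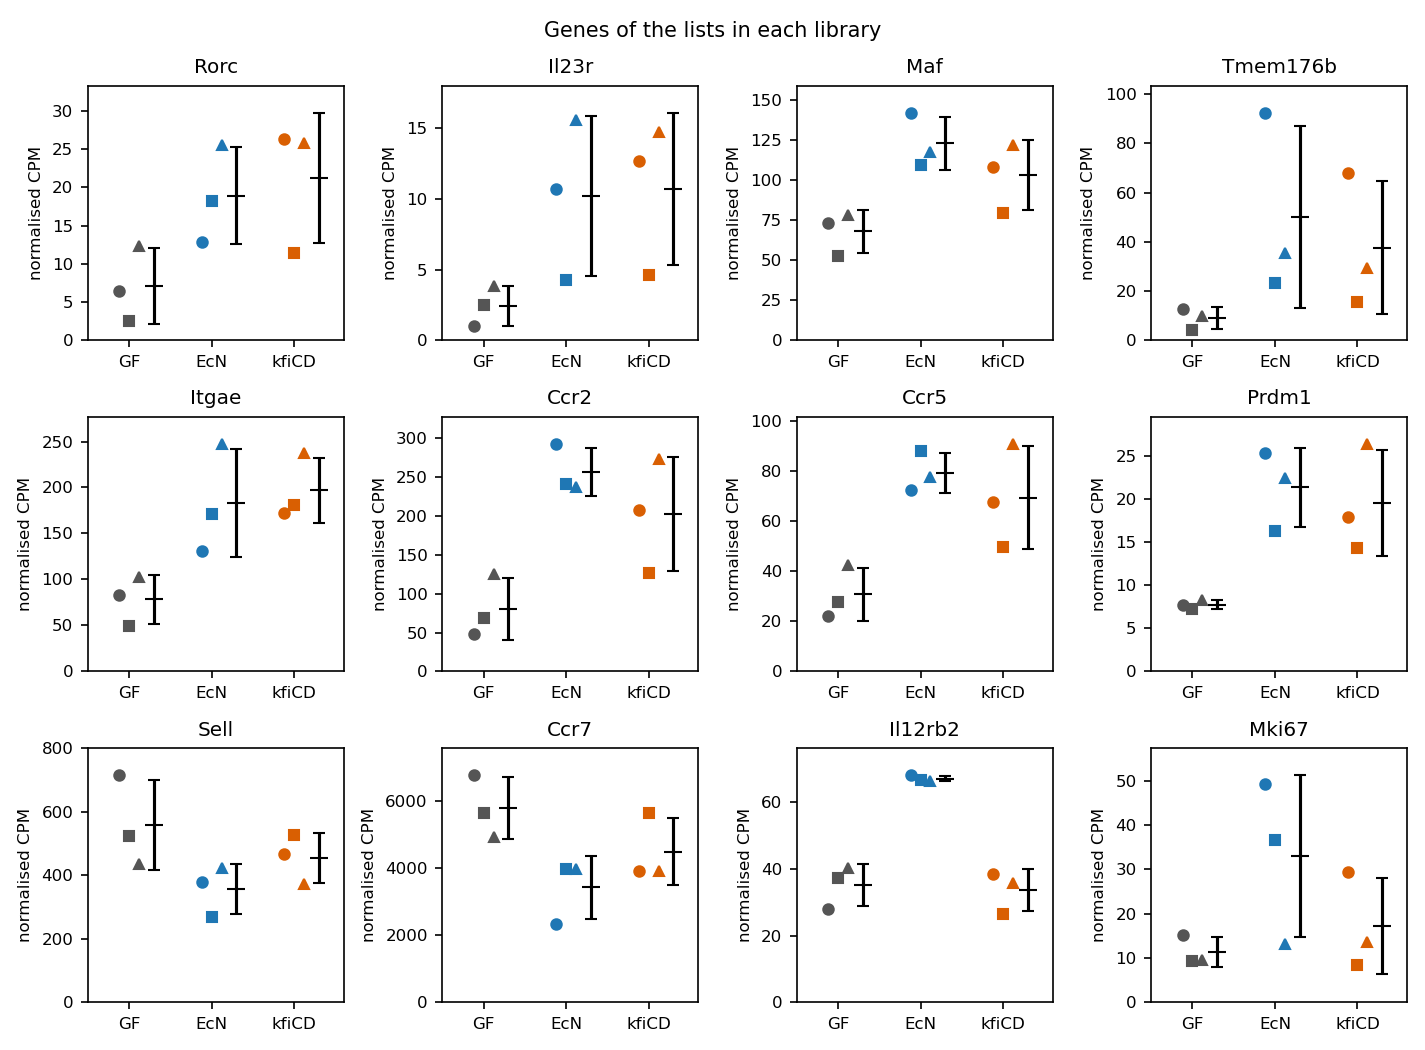
Normalised CPM (vertical axis) of 12 genes in GF, EcN and kfiCD, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD of 3 libraries. Itgae was at 78.4, 183 and 197 CPM, and Il12rb2 at 35.3, 67.2 and 33.7 CPM.

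Over all genes tested, factors of helper T cell lineages and effector cytokines did not pass in EcN against GF. This held for Rorc too (edgeR adjusted p = 0.448), which passed only when adjusted over its list. Tbx21, the Th1 factor, had a log2 fold change of 0.64 ± 0.63, Gata3, the Th2 factor, of 0.58 ± 0.27, and Bcl6, the follicular helper factor, of -0.32 ± 0.26. The cytokine genes Il17a and Ifng were low, at 1.48 ± 2.10 against 0.793 ± 1.16 CPM and 4.33 ± 3.44 against 1.97 ± 2.31 CPM, and the activation marker Cd69 had a log2 fold change of 0.35 ± 0.27. Mki67, a marker of dividing cells, was at 33.0 ± 18.3 against 11.4 ± 3.31 CPM (adjusted p = 0.374). Il22, a cytokine that acts on the epithelium, was too low to test. It had 0 counts in each GF library. EcN replicates 1, 2 and 3 had 16, 8 and 0 counts, and kfiCD replicates 1, 2 and 3 had 117, 1 and 0. A count of 0 allows up to 3 counts, or 0.577 to 0.774 CPM in the GF libraries, a limit that covers counting error only.

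The comparison of kfiCD with GF asked what the strain without capsule did. Th17 genes rose here too. All 12 lay above GF with a median log2 fold change of 1.91 (camera adjusted p = 8.66e-16, and adjusted p = 0.0610 with an estimated correlation). Rorc stood at 21.2 ± 8.48 against 7.09 ± 4.95 CPM (2.95-fold, n = 3) and Il23r at 10.7 ± 5.36 against 2.46 ± 1.41 CPM. Il1r1, the receptor through which IL-1 promotes Th17 cells, was at 7.23 ± 0.671 against 0.601 ± 0.687 CPM. Gut homing and residency genes rose (12 of 16, median 0.43, adjusted p = 2.54e-06, and adjusted p = 0.402 with an estimated correlation). Itgae was at 197 ± 35.5 against 78.4 ± 26.7 CPM and Ccr5 at 69.3 ± 20.6 against 30.7 ± 10.5 CPM. Adjusted over the list alone, 8 Th17 genes (Rorc, Il23r, Il1r1, Ahr, Maf, Tmem176a, Tmem176b and Il17re) and 4 residency genes (Itgae, Ccr5, Ccr2 and Prdm1) passed, and 0 passed over all genes tested. The naive list fell (14 of 15 below GF, median -0.21, adjusted p = 0.00215, and adjusted p = 0.593 with an estimated correlation). Interferon response (20 of 23 above, median 0.28, adjusted p = 0.000641), T cell receptor activation (17 of 20, median 0.19, adjusted p = 0.00138) and co-inhibitory receptor genes (8 of 11, median 0.40, adjusted p = 0.0182) rose. For each of these the value was adjusted p = 0.593 with an estimated correlation. Regulatory T cell genes rose (11 of 18, median 0.34, adjusted p = 0.0158, and adjusted p = 0.726 with an estimated correlation). So did cholesterol synthesis genes (17 of 20, median 0.11, adjusted p = 0.0338, and adjusted p = 0.593 with an estimated correlation). Hmgcr, the rate-limiting enzyme, was at 215 ± 7.03 against 127 ± 33.3 CPM. Adjusted over the list alone, Hmgcr passed, and 0 genes of the naive, interferon, activation, co-inhibitory and regulatory lists did. For kfiCD replicates 1, 2 and 3, interferon scored 0.56, -0.20 and 0.66, and activation 0.59, -0.07 and 0.38. The regulatory list scored 0.37, -0.24 and 0.47, and the naive list -0.42, 0.05 and -0.28. kfiCD replicate 2 thus lay below all GF libraries for interferon and activation, and within the GF range for regulatory and naive genes. Dissociation stress scored 0.33, -0.44 and 0.38, and a part of handling was not tested. Only 4 lists were called without kfiCD replicate 1 and 4 without kfiCD replicate 3, and 14 were called without kfiCD replicate 2. Of the 8 lists, 3 kept their call without kfiCD replicate 1, the library with fibroblast transcripts and olfactory receptor reads.

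**Figure D4:**
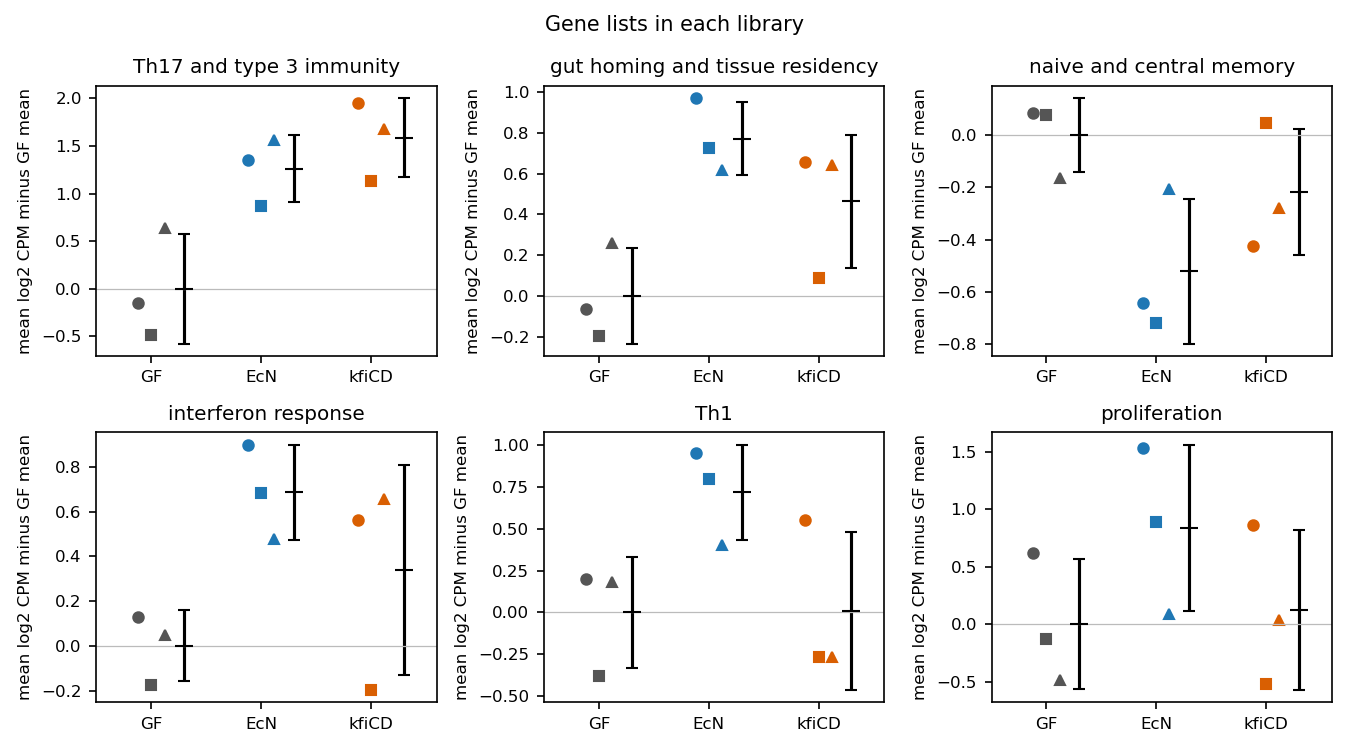
Score of 6 gene lists in each library, as the mean log2 CPM of the list minus the mean of the GF libraries (vertical axis), with bars for mean ± SD of 3 libraries and circles, squares and triangles for replicates 1, 2 and 3. For the Th17 list, all 6 libraries of colonized mice lay above all 3 GF libraries.

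In kfiCD against GF, edgeR called 0 genes, and 180 with no low-count filter. There were 697 at an unadjusted p under 0.05 (490 higher and 207 lower), and other splits of these 6 libraries gave from 312 to 798. DESeq2 called 15, among them Itgae, Ccr5, Il1r1 and Hmgcr, and limma-voom 0. The lowest adjusted p was 0.523, for Cipc (69.5 ± 2.77 against 38.9 ± 3.57 CPM) and Frmd6, a FERM domain gene (75.9 ± 4.80 against 40.6 ± 3.93 CPM). Dnmt1, the maintenance DNA methyltransferase, had a log2 fold change of 0.83 ± 0.18 and Mbnl1, a splicing regulator, of 0.56 ± 0.12. Pik3ip1, an inhibitor of PI3 kinase, lay below GF at 129 ± 17.2 against 225 ± 12.8 CPM. Further genes of low p below GF were Xpnpep1 (-0.64 ± 0.15), Commd9 (-1.38 ± 0.38), Phc3 (-0.54 ± 0.15) and Dkc1, a subunit of telomerase (-0.59 ± 0.17), none of which passed. Among lineage and effector genes, none passed over all genes tested, Rorc included (edgeR adjusted p = 0.695). Foxp3 had a log2 fold change of 0.30 ± 0.26, Tbx21 of 0.12 ± 0.64, Gata3 of 0.06 ± 0.27, Bcl6 of -0.05 ± 0.25, Il17a of 1.74 ± 1.14 and Ifng of -0.92 ± 1.18. Il10 was at 1.11 ± 0.35, Cd69 at 0.40 ± 0.27, Cd44 at 0.65 ± 0.22, Sell at -0.29 ± 0.20, Mki67 at 0.60 ± 0.50 and Gzmb at 1.10 ± 0.37 on the same scale. The libraries of the groups were fully apart for 646 genes upward and 592 downward, 10.4% where chance gives 10%. Cipc lies on chromosome 12 from 86947043 to 86965362 and Frmd6 on the same chromosome from 70825514 to 70902234. Nmrk1 lies on chromosome 19 from 18631950 to 18652428, and Furin on chromosome 7 from 80388585 to 80405436.

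The fold changes of both strains against GF were positively correlated across genes, which a common GF group alone also brings about. Among genes at an unadjusted p under 0.05, 270 were higher than GF with both strains and 61 lower with both, Cipc, Itgae, Ccr5, Ccr2 and Prdm1 among the former. Both comparisons use the same GF libraries. Simulated libraries without group differences, also compared with a common GF group, gave 70.1 ± 6.97 and 45.8 ± 6.57 genes (mean ± SD of 20 draws). Independent lists of these sizes would share 26.5 and 6.45. Pearson's correlation of the log2 fold changes across genes, which are not independent replicates, was 0.653 against 0.491 ± 0.0186 simulated. Their covariance was 0.199 against 0.0973 ± 0.00467. The 3 controls could not be split, so part of the excess may come from the shared controls. The simulation also lacks signals that real libraries share, such as fibroblast transcripts in EcN replicate 1 and kfiCD replicate 1. The excess therefore cannot decide whether the response to the strains was shared. The correlation was 0.365 without kfiCD replicate 1.

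The direct comparison of kfiCD with EcN asked what differed between the strains. Camera called 10 lists. Of 10 splits of these 6 libraries, the real one included, 4 gave at least as many, and the highest other gave 14. The list calls therefore do not show an effect of the capsule. Th1 genes were lower with the mutant (11 of 12 below EcN, median -0.52, camera adjusted p = 9.12e-06, and adjusted p = 0.391 with an estimated correlation). Il12rb2 was at 33.7 ± 6.34 CPM in kfiCD and 67.2 ± 0.858 in EcN (0.501-fold, n = 3), while GF had 35.3 ± 6.43 CPM. It was the 1 Th1 gene to pass when adjusted over the list alone. It lies on chromosome 6 from 67291318 to 67376188 and shares 1519 exon bases with Serbp1 on the opposite strand, whose log2 fold change was -0.11. Reads of this part could not be assigned without strand. Proliferation genes fell (21 of 22 below EcN, median -0.51, adjusted p = 6.32e-07, and adjusted p = 0.391 with an estimated correlation), with Mki67 at 17.2 ± 10.9 against 33.0 ± 18.3 CPM. Interferon response genes fell (19 of 23, median -0.26, adjusted p = 0.000345), as did residency genes (14 of 16, median -0.22, adjusted p = 0.00229), and naive genes rose (13 of 15, median 0.32, adjusted p = 4.91e-06). For each of these lists the value was adjusted p = 0.391 with an estimated correlation. The Th2 list fell (8 of 8, median -0.60, adjusted p = 0.00266, and adjusted p = 0.445 with an estimated correlation). Its median was 0.03 without EcN replicates 1 and 2 and kfiCD replicate 1, a set chosen after seeing the data that leaves 1 EcN library, and its score was 2.00 in EcN replicate 1 but -0.74 in EcN replicate 3. The cytotoxic list fell (12 of 14, median -0.17, adjusted p = 0.0278, and adjusted p = 0.391 with an estimated correlation). The NF-kB list fell (16 of 17, median -0.17, adjusted p = 0.000632, and adjusted p = 0.517 with an estimated correlation). So did the regulatory T cell list (15 of 18, median -0.19, adjusted p = 0.0197, and adjusted p = 0.776 with an estimated correlation). Without kfiCD replicate 2 its median was -0.00034, and camera's direction turned upward. The list of CD8, gamma-delta and innate lymphocyte genes rose (4 of 5 measured, median 0.63, adjusted p = 0.0427, and adjusted p = 0.391 with an estimated correlation). Its member Cd8b1, a CD8 chain, was at 21.5 ± 7.72 against 13.9 ± 5.28 CPM. GF replicates 1, 2 and 3 had 13.2, 24.9 and 23.1 CPM of Cd8b1 before scaling. The other CD8 chain, Cd8a, was at 0, 0 and 0.26 CPM in kfiCD and 0.95, 0 and 0 in EcN, so more CD8 cells with the mutant were not shown. The Th17 list did not pass between the strains (7 of 12 above EcN, median 0.11, adjusted p = 0.602). Adjusted over the list alone, 0 genes of the other called lists passed, and over all genes tested 0 passed. The libraries of the strains overlapped for several of these scores. For replicates 1, 2 and 3, Th1 scored 0.96, 0.80 and 0.40 in EcN and 0.55, -0.26 and -0.27 in kfiCD. Interferon scored 0.90, 0.68 and 0.48 against 0.56, -0.20 and 0.66, and residency 0.97, 0.73 and 0.62 against 0.66, 0.09 and 0.64. Proliferation scored 1.53, 0.89 and 0.09 in EcN and 0.86, -0.52 and 0.03 in kfiCD. The naive list scored -0.64, -0.72 and -0.21 against -0.42, 0.05 and -0.28, and NF-kB targets 0.52, 0.38 and -0.002 against 0.43, -0.28 and 0.05. Of the 10 lists, 3 kept their call without EcN replicate 1, which held plasma cell and fibroblast transcripts, and 3 without kfiCD replicate 2.

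Gene by gene, edgeR and limma-voom called 0 genes between the strains, as did DESeq2, while edgeR with no low-count filter called 65. At an unadjusted p under 0.05 edgeR gave 404, fewer than the 597 that chance gives. Besides Il12rb2, the genes of lowest p below EcN were Il12rb1, the other chain of the IL-12 receptor (57.4 ± 0.582 against 107 ± 39.6 CPM), Rttn (-1.31 ± 0.35), Paqr8 (-1.26 ± 0.35) and Lpxn, the adhesion adaptor leupaxin (-0.63 ± 0.18). Above EcN lay Tmem63a (0.62 ± 0.14), Ssh3, a cofilin phosphatase (1.71 ± 0.38), Ifi206 (2.51 ± 0.60), Plekhg2 (0.84 ± 0.20) and Tmem50b (0.62 ± 0.16), all at adjusted p = 0.999. Ifi206 belongs to a family of near-identical genes among which reads could be divided. Lineage and effector genes did not pass either. Foxp3 had a log2 fold change of -0.22 ± 0.26, Rorc of 0.16 ± 0.47, Tbx21 of -0.53 ± 0.63, Gata3 of -0.52 ± 0.27, Bcl6 of 0.26 ± 0.26, Il17a of 0.92 ± 1.10 and Ifng of -2.08 ± 1.15. On the same scale Il10 was at 0.06 ± 0.35, Cd69 at 0.04 ± 0.27, Cd44 at -0.28 ± 0.21, Sell at 0.35 ± 0.20 and Gzmb at -0.21 ± 0.36. The groups were fully apart for 545 genes upward and 482 downward, 8.60% where chance gives 10%. A test of any difference among the 3 groups called 0 genes with edgeR (739 at an unadjusted p under 0.05), 67 with DESeq2 and 0 with limma-voom. For genes that differ among the 3 groups, edgeR with no low-count filter gave 331.

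The use of T cell receptor beta V segments was compared as a measure of how narrow the repertoire was. The most used Trbv segment held 12.4 ± 1.01% of Trbv reads in GF, 14.3 ± 2.53% in EcN and 13.6 ± 1.39% in kfiCD (n = 3 each). Exact permutation tests (both directions counted) gave p = 0.3 for EcN against GF, p = 0.4 for kfiCD against GF and p = 0.9 between the strains, where 3 against 3 libraries cannot go below 0.1. Trbv19 was the most used segment in 7 of the 9 libraries and Trbv1 in GF replicate 3 and kfiCD replicate 3. The effective number of Trbv segments was 16.3 ± 0.475 in GF, 15.6 ± 0.766 in EcN and 15.4 ± 0.957 in kfiCD.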

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

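Chosen after the result was seen were the marker, depth and whole-group tests of plasma cell and fibroblast transcripts, the depth test of silent-gene reads, and the tests of list calls without single libraries or sets of libraries.

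The responses to the strains against GF differed by camera in 10 lists, given as kfiCD minus EcN in median log2 fold change, and 0 of these calls held with an estimated correlation. The differences were -0.19 for regulatory T cell, -0.52 for Th1, -0.60 for Th2, 0.32 for naive and central memory, -0.17 for cytotoxic effector, -0.26 for interferon response, -0.51 for proliferation, -0.17 for NF-kB, -0.22 for gut homing and residency, and 0.63 for CD8, gamma-delta and innate lymphocyte genes. Without EcN replicate 1 the count was 3 and without kfiCD replicate 2 it was 5. Outside the comparisons, Il22 had 117 counts (28.6 CPM) in kfiCD replicate 1 but 1 and 0 counts in kfiCD replicates 2 and 3. EcN replicates 1, 2 and 3 had 16, 8 and 0 counts, and all GF libraries had 0.

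EcN replicate 1 held antibody transcripts, with Igha at 7600 CPM, Igkc at 5675 and Jchain, which joins antibody units, at 1656, and fibroblast markers summed to 1165 CPM there and to 2522 CPM in kfiCD replicate 1, where the collagen gene Col3a1 was at 704 CPM. The tables argue against depth and against a response of the whole colonized group: the larger of the 2 libraries had 0.809 times the highest total of the others, and the lowest colonized library had 0.516 times the summed markers of the highest GF library. RNA of plasma cells and fibroblasts may be the source, since 11 of 14 plasma cell markers (78.6%) in EcN replicate 1 and 16 of 16 fibroblast markers in both libraries lay at least 3 times above the libraries without the signal. Whole plasma cells or fibroblasts should have been removed by the gate on CD4 and the T cell receptor, so free RNA, attached cells and gate impurity stay open. A biological difference between these samples was not tested.

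Olfactory receptor genes summed to 1416 CPM in EcN replicate 2 and 966 CPM in kfiCD replicate 1, against 134 to 251 CPM in the other libraries, and vomeronasal receptor genes followed them. The tables argue against depth, since the larger of these libraries had 0.787 times the highest total of the others, and against expression of a few receptor genes, since the 10 with most reads held 4.36% of the excess. Reads spread over the genome, such as genomic DNA, are a candidate explanation: 9 other silent families, among them taste receptors and defensins, summed to 49.1 and 41.8 CPM in these libraries, the lower being 2.62 times the highest of the others. The source of such reads was not tested, nor was a biological explanation.

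The shifts of gene lists between colonized and GF mice could come from these libraries instead of colonization. For EcN against GF most calls did not rest on either library alone. Of the 12 called lists, 83.3% kept their call without EcN replicate 1 and 100% without EcN replicate 2. Leaving out a library tests only camera's calls at the preset correlation. With an estimated correlation, 0 of them held. Each test left the other library in, and without EcN 1, EcN 2 and kfiCD 1 58.3% kept their call, but 1 EcN library is too few to decide, so a joint share of these libraries stays open. For kfiCD against GF, 37.5% of the 8 lists kept their call without kfiCD replicate 1, and 37.5% also without kfiCD replicate 3, which shows neither signal, so the share of the shift that rests on kfiCD replicate 1 stays open. Colonization stays among the open explanations.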

How the results depend on the processing

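Tests without the libraries EcN 1, EcN 2 or kfiCD 1 taken in sets were chosen after seeing the data. The counts of 0 genes in edgeR moved with the filter and the tool. With no low-count filter they were 313 for EcN against GF, 180 for kfiCD against GF, 65 for kfiCD against EcN and 331 for genes that differ among the 3 groups, and DESeq2 gave 101, 15 and 67 for all but kfiCD against EcN. For EcN against GF, a strict filter gave 5 genes, with fewer genes to adjust over, a robust fit 5, and a threshold of 0.1 gave 10. Otherwise the cause was not tested. The replicate block gave 18 genes for EcN against GF, all higher, 14 of them also called by DESeq2, and it changed no other gene count and gave 12, 8 and 9 lists against 12, 8 and 10. Of 9 pairs of libraries with the same number, 3 had correlated deviations over 0.1, and 4 of 9 libraries matched their own number best, so the numbers were not used to pair the samples. The labels do not say if they share a day or litter.

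With an estimated correlation and with fry's directional test, 0 lists were called in all 3 comparisons. Fry's mixed test called 6 for EcN against GF, 1 for kfiCD against GF and 0 for kfiCD against EcN. These tests allow for genes that vary together, but they also differ in what they ask, and the cause was not tested. Leaving out 1 library gave 10 to 17 lists for EcN against GF, 4 to 14 for kfiCD against GF and 3 to 12 for kfiCD against EcN, and 0 genes in each comparison. For kfiCD against GF, 3 lists were called without EcN 1 and kfiCD 1, 3 without EcN 2 and kfiCD 1, and 3 without all of these, where kfiCD against EcN gave 2 with only 1 EcN library left. Camera's direction reversed, at a median of -0.00034 (camera upward), for regulatory T cell genes in kfiCD against EcN without kfiCD replicate 2, within -0.361 to 0.0163 when leaving out 1 library. It also did without EcN 1, EcN 2 and kfiCD 1, at -0.10 for Th2, -0.0284 for proliferation and 0.0106 (camera downward) for NF-kB in EcN against GF, and 0.0339 for Th2 in kfiCD against EcN. The cause was not tested. Correlation of the responses was 0.564 by Spearman's measure, and 0.365 to 0.847 with 1 library left out. Single genes stayed on their side of the threshold in 1448 alternatives, in which their direction was not checked, and passed it in 60. Lists kept their direction and call in 374 and lost their call in 131. At 1.5-fold, few changed genes could be recovered at this spread.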

Other observations

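Chosen after the results were seen were the comparison of all colonized mice with GF mice, and its exact tests.

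The 6 libraries of colonized mice, pooled over strains, lay above all 3 GF libraries for the score of the Th17 list, by 1.42 log2 units (exact permutation p = 0.0119, the smallest that 84 splits allow, and 0.175 when adjusted over 22 lists). The camera call of this list held with an estimated correlation (adjusted p = 0.0281, median 1.60). That of gut homing and residency did not (adjusted p = 0.153 with an estimated correlation, median 0.60). Cholesterol synthesis genes scored 0.18 higher on average, with 6 of 6 libraries above all GF libraries, and residency genes 0.62 higher on average with 5 of 6 above (exact p = 0.0238 each, adjusted 0.175). Cipc was at 74.5 ± 6.39 CPM in colonized and 38.9 ± 3.57 CPM in GF mice, and Il1rn, which encodes the IL-1 receptor antagonist, at 5.81 ± 2.25 and 0.0756 ± 0.131 CPM (adjusted p = 0.0671 each in edgeR). Asb2, a ubiquitin ligase component, was at 209 ± 43.5 against 105 ± 20.6 CPM, Prdm1, which encodes the effector regulator Blimp-1, at 20.4 ± 4.97 against 7.76 ± 0.516 CPM. Pik3ip1 was at 139 ± 25.6 against 225 ± 12.8 CPM. In this grouping edgeR called 0 genes (960 at an unadjusted p under 0.05) and no other tool was run. Beyond all GF libraries, 238 genes lay wholly above and 189 wholly below GF, 3.58% where chance gives 2.38%. Camera called 13 lists, of which only Th17 held with an estimated correlation, the other 12 then having adjusted p from 0.153 to 0.554.

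Metabolic and other lists did not pass in EcN against GF. Medians were 0.11 for glycolysis (adjusted p = 0.248), -0.06 for oxidative phosphorylation (adjusted p = 0.237), 0.18 for cholesterol synthesis (adjusted p = 0.0550) and 0.10 for the unfolded protein response (adjusted p = 0.0906). T follicular helper genes had a median of -0.03 and a mean of 0.11 (adjusted p = 0.597), dissociation stress genes a median of 0.17 (adjusted p = 0.237). The stress score differed between libraries of a group, at 0.43, 0.31 and -0.36 in EcN replicates 1, 2 and 3 and 0.33, -0.44 and 0.38 in kfiCD. In both groups its lowest library was also the lowest for the activation, NF-kB and regulatory lists. The GF libraries went the other way, with replicate 1 lowest for stress (-0.34) but highest for activation (0.10) and NF-kB (0.02). Lists of other cells had medians of 0.51 for B and plasma cells (adjusted p = 0.247), -0.44 for macrophages and dendritic cells (adjusted p = 0.866), 4.46 for stromal and endothelial cells (adjusted p = 0.935) and -0.33 for CD8, gamma-delta and innate lymphocytes (adjusted p = 0.597). Neutrophil and mast cell genes, not tested as a list, summed to 93.3, 102 and 83.1 CPM in EcN replicates 1, 2 and 3. In GF they summed to 44.4, 45.3 and 67.8 CPM, and most of each sum was Mmp9 and Kit.

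In kfiCD against GF the Th1 list had a median of -0.03, while camera's direction was upward (adjusted p = 0.558), and Th2 genes a median of 0.23 (adjusted p = 0.551). Medians were 0.25 for proliferation (adjusted p = 0.464), 0.17 for cytotoxic genes (adjusted p = 0.237), 0.05 for NF-kB (adjusted p = 0.558) and 0.03 for T follicular helper (adjusted p = 0.651). They were 0.04 for glycolysis (adjusted p = 0.558), -0.07 for oxidative phosphorylation (adjusted p = 0.115), 0.03 for the unfolded protein response (adjusted p = 0.558) and 0.14 for dissociation stress (adjusted p = 0.228). Lists of other cells stood at 0.15 for B and plasma cells (adjusted p = 0.689), -0.12 for macrophages and dendritic cells (adjusted p = 0.558), 6.68 for stromal and endothelial cells (adjusted p = 0.657) and 0.37 for CD8, gamma-delta and innate lymphocytes (adjusted p = 0.268). In kfiCD against GF, 4 stromal genes passed as higher when adjusted over the list alone, among them Col3a1, which was at 704 CPM in kfiCD replicate 1, and Pecam1 as lower, with 0 over all genes tested. In kfiCD against EcN, T follicular helper genes had a median of 0.02 and a mean of -0.03 (adjusted p = 0.900), T cell receptor activation a median of -0.10 (adjusted p = 0.310), and co-inhibitory receptors of -0.08 (adjusted p = 0.305). Glycolysis had a median of -0.08 (adjusted p = 0.573), oxidative phosphorylation of -0.03 (adjusted p = 0.734), cholesterol synthesis of 0.03 (adjusted p = 0.960), the unfolded protein response of -0.05 (adjusted p = 0.224) and dissociation stress of 0.02 (adjusted p = 0.960). B and plasma cell genes stood at -0.66 (adjusted p = 0.310), macrophage and dendritic cell genes at -0.08 (adjusted p = 0.697) and stromal and endothelial genes at 0.91 (adjusted p = 0.543).

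Among immunoglobulin V segments in EcN replicate 1, Igkv12-41 held 25.5% of V reads, Igkv3-7 17.7%, Ighv1-54 15.4%, Ighv1-75 15.3%, Igkv10-96 12.1% and Ighv9-3 10.6%.

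Other splits of the samples were also fitted. With 10 splits of 6 libraries a share under 0.05 cannot be reached. For genes in edgeR, the real split gave 0 in all 3 comparisons and the highest other split 0 for EcN against GF, 1 for kfiCD against GF and 27 for kfiCD against EcN. With a real count of 0, 10 of 10 splits give as many in each whatever the data, so these counts test nothing. The split with 27 genes sets EcN replicates 1 and 2 and kfiCD replicate 1 against the rest, which points to a structure of the samples along the libraries that stand apart. For lists, the real split gave 12 and the highest other 15 for EcN against GF (3 of 10 as large), 8 and 15 for kfiCD against GF (5 of 10), and 10 and 14 for kfiCD against EcN (4 of 10). Among the 3 groups, 21 of 100 drawn splits gave at least the 739 genes at an unadjusted p under 0.05 (highest other 1647), so chance was not excluded. For colonized against GF, 11 of 84 splits gave at least 13 lists (highest other 18), so chance was not excluded there either. For genes at an adjusted p under 0.05 the real counts were 0, which all 100 of 100 and 84 of 84 splits reach by necessity (highest others 136 and 140), so these say nothing about chance. Splits with 136 and 140 genes, where the real ones had 0, point to structure as well, and the one with 140 again sets EcN replicates 1 and 2 and kfiCD replicate 1 apart.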
